A study of Homo sapiens with 6 samples.

How the data were processed

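Expression was measured by strand-specific mRNA sequencing in PC-9 cells, an EGFR-mutant human lung cancer cell line. Per the labels, 3 samples carried the pCMV3 vector and 3 carried stable overexpression of macroH2A1.2, a splice isoform of the histone variant macroH2A1. Per the labels' protocols, both kinds of cell were grown with 200 µg/ml hygromycin as the selection agent, and libraries had inserts of 250 to 300 bp and were made by a commercial provider. The submitters' processing notes name STAR, HTSeq, DESeq2 and the hg19 genome build, with no versions or roles. Whether counting used the strand is not given in the sources used here.

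The deposited table held raw read counts per gene for each library, which the authors had not normalized, per the file headers and the whole-number values. It also held FPKM values, which the authors had scaled by gene length and library size, per the file headers: 2 columns of group means, and 6 columns per library that carry the same library names as the counts and were not mapped to samples. No FPKM value was used. The authors' deposited table of the comparison gave group means of normalized counts (a signal on the scale of counts), log2 fold changes, p-values and adjusted p-values. Coordinates and gene classes were taken from the same table, in hg19. The 6 count columns named the group and a number from 1 to 3, but not which sample within the group. Total counts ran from 32356038 to 39872291 per library over 48162 genes. Reads carried no stated molecular identifiers, so counting intervals and floors cover counting error only.

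Counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes with too few counts were removed with filterByExpr, which left 15380 genes; libraries were scaled by TMM; and macroH2A1.2 was compared with vector by a robust, two-sided quasi-likelihood F test over all 6 libraries with group as the single term. P-values were adjusted by the Benjamini-Hochberg method, and a gene was called at an adjusted p under 0.05. The standard error of a log2 fold change was its size divided by the square root of F. CPM values are TMM-normalized and given as mean ± SD of 3 libraries. For a gene with 0 counts in a group, the fold is a lower bound against a floor of 3 counts over that group's 3 libraries. For 1 to 3 counts, the ratio is given with its 95% exact binomial interval. The pipeline was tested on simulated counts with known changes for this comparison: in 15380 genes it called 52 of 58 genes changed 4-fold, 51 of 66 changed 2-fold and 25 of 76 changed 1.5-fold, and 13 of 15180 unchanged genes. In simulated data with 1 shifted list, the list test called that list and 0 others. Genes were simulated independently, without correlation between genes or differences shared by same-numbered libraries. This result therefore does not show how the list test behaves on the real libraries. With the observed log2 fold changes permuted over gene positions and 3 windows then shifted by 0.5 (log2), the window test called those 3 and 0 others. Permuting removes whatever neighbouring genes share, so this does not show how the test behaves where neighbours vary together. Many shifted windows in the data had medians smaller than 0.5, for which this gives no rate of calls.

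There were 34 gene lists, written before the data were examined, of which 30 had at least 5 tested genes. They were tested with camera in limma 3.58.1 on voom values at a preset inter-gene correlation of 0.01, and again with an estimated correlation and with fry, which tests whether a list's genes move on balance in 1 direction and does not compare them with other genes. Neighbouring tested genes were grouped into 299 windows of about 50 along each chromosome, and each window's median log2 fold change was set against 10000 draws of genes from other positions. That window test was planned for the closing section; its counts also stand in the report because called genes named there lie in shifted windows. A reference annotation of another build was used for transcript GC content by gene identifier, available for 97.2% of tested genes, and for no coordinates. Gene classes among called genes were compared by Fisher's exact test, two-sided.

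Named genes followed a rule fixed before the data were examined. It took H2AFY, the gene of macroH2A1; the 12 largest rises and the 12 largest falls among called protein-coding genes with a gene-like symbol, a mean of at least 5 CPM in the higher group and all libraries of one group above all of the other; up to 4 called members of each list by lowest adjusted p; the 6 genes with the lowest adjusted p at 5 CPM or more; and EGFR, VIM, CDH1, MKI67, H2AFY2 and PARP1. Other names are marked as chosen after their values were seen.

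The column numbers were shared by both groups, so pairing was checked before the fits were compared. Over 9775 genes, deviations from the group mean of same-numbered libraries correlated at 0.676, 0.346 and 0.483, and those of other pairs ran from -0.507 to -0.0027. The numbers thus appear to pair the libraries across groups, though the labels do not say what a number stands for. The main fit does not use this pairing, so its calls, standard errors and p-values leave it out. The comparison had been set without a block before the data were examined and was kept so; the fit with the number as a replicate block was run as an alternative. No library was a duplicate of another: within groups, the chi-square of counts per degree of freedom ran from 20.4 to 83.2. Further alternatives were other scalings, other count filters, DESeq2 1.42.0, limma voom, a non-robust fit, leaving out each library and, chosen after the data were seen, leaving out shifted windows or read-sharing gene families. Figures were drawn with matplotlib 3.10.9.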

Results

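The data are gene-level mRNA read counts from PC-9 cells, an EGFR-mutant lung cancer line, in 2 groups of 3 libraries. One group carried the pCMV3 vector and the other stably overexpressed macroH2A1.2, an isoform of a histone variant in which a large macrodomain follows the histone fold. Each library held between 32356038 and 39872291 counts, with means of 35051400 ± 4184710 in vector and 33614100 ± 1549780 in macroH2A1.2 cells (SD, n = 3). The 10 most counted genes took 4.83% ± 0.0835 of counts in vector and 4.77% ± 0.161 in macroH2A1.2 libraries (SD, n = 3). Log2 CPM values of 15380 genes correlated at 0.982 to 0.992 between libraries of one group and at 0.949 to 0.962 between groups. The first principal component held 69.0% of the variance and parted the groups; the second held 15.4% and ordered the libraries alike in both groups by the number in the count table. The labels do not say that the libraries came from separate cultures, so p-values measure the spread between these libraries, which may be technical. The samples of a group share 1 description (C1 for vector, C17 for macroH2A1.2), and the labels do not say whether these are clones or pools. Each group is therefore taken as 1 selected line. A difference between the lines cannot be told apart from an effect of the construct.

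The comparison asks which transcripts differ when macroH2A1.2 is overexpressed. H2AFY (MACROH2A1, ENSG00000113648, hg19 chromosome 5, 134669590 to 134735604), the gene that encodes macroH2A1, had 8754, 6728 and 7497 counts in the vector libraries and 43262, 48636 and 32175 in the macroH2A1.2 libraries. Its level rose from 223 ± 7.15 to 1204 ± 215 CPM (SD, n = 3), a log2 fold change of 2.43 ± 0.15 (SE; 5.41-fold; adjusted p = 7.39e-05, edgeR quasi-likelihood test with Benjamini-Hochberg adjustment, as for every single-gene adjusted p given here). It lay in a window of neighbouring genes with a median log2 fold change of 0.17. Gene counts do not tell the 1.2 isoform from 1.1, nor the construct from the endogenous gene. The authors' deposited table gave H2AFY a log2 fold change of 2.33 with an adjusted p of 7.97e-49. H2AFY2, which encodes macroH2A2, had 35 counts over the vector libraries and 23 over the macroH2A1.2 libraries and was too low to test.

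Of 15380 genes tested, 3248 changed (21.1%), 1535 higher and 1713 lower in macroH2A1.2 cells. Of these, 1195 changed at least 2-fold (609 higher and 586 lower) and 251 at least 8-fold (106 higher and 145 lower). The groups did not overlap for 3240 of the 3248 called genes and for 39.0% of all tested genes, where chance gives 10%. That 10% takes the libraries as exchangeable and leaves out what same-numbered libraries share. Protein-coding genes made up 2909 of the calls: 22.8% of coding genes were called against 13.1% of other genes (odds ratio 1.96, adjusted p = 9.32e-30, Fisher's exact test). Coding genes took at least 98.38% of each library's counts, and the test neither matches depth nor allows for neighbouring genes that shift together. Among genes changed at least 2-fold the odds ratio of coding genes was 0.881 (adjusted p = 0.12, Fisher's exact test). At 2-fold, long intergenic noncoding genes had an odds ratio of 1.99 (adjusted p = 1.98e-06) and pseudogenes one of 0.69 (adjusted p = 0.0295, Fisher's exact test). With the library number as a block, 5260 genes were called, 2596 higher and 2664 lower, 3239 of them among the 3248. Without vector library 2 the count was 1976, and without macroH2A1.2 library 2 it was 1837. The authors' deposited table marked 3733 genes; 3607 of them were tested here, and 3187 were called here, all 3187 in the same direction.

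The 12 largest rises and 12 largest falls followed the naming rule and form no tested group. SDK1, an immunoglobulin-superfamily adhesion gene, had 2 counts over the vector libraries and 28.3 ± 5.41 CPM in macroH2A1.2 cells (SD, n = 3), a ratio of 1460 (95% counting interval 405 to 12100). L1CAM, a neural cell adhesion molecule, rose from 0.705 ± 0.219 to 167 ± 23.1 CPM (log2 fold change 7.87 ± 0.22, SE, adjusted p = 3.85e-06), and NTN1, the guidance cue netrin-1, rose by 5.01 on the log2 scale. KYNU, a kynurenine pathway enzyme, rose from 2.15 ± 0.0834 to 65.3 ± 15.6 CPM (log2 fold change 4.92 ± 0.20, SE, adjusted p = 1.43e-05). The other genes among the 12 largest rises were PDZD2, RASGRF1, MGAT4A, ADCY5, TRPM2, NEURL1B, ARRB1 and PPFIBP2, with log2 fold changes from 4.56 to 5.67 and adjusted p from 1.93e-05 to 0.00142. SDK1 and PDZD2 lay in stretches of chromosome where genes shifted upward together, and ARRB1 in a stretch that shifted downward. TNC, the matrix protein tenascin-C, was among the 6 lowest adjusted p and rose from 21.4 ± 1.57 to 168 ± 6.19 CPM (log2 fold change 2.97 ± 0.098, SE, adjusted p = 7.45e-06). The clone-named gene RP11-274K13.5 on chromosome X also belonged to those 6, with a log2 fold change of 7.57 ± 0.30 (SE, adjusted p = 1.43e-05), in a window with a median of 0.17.

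Of the 12 largest falls, SUMF1, RPE65 and OR51B4 had 0 counts in each macroH2A1.2 library. SUMF1, which encodes the sulfatase-activating enzyme, was at 14.2 ± 1.25 CPM in vector cells and at least 484-fold lower in macroH2A1.2 cells (adjusted p = 3.62e-05). Its neighbours SETMAR, which lies within SUMF1 on the opposite strand, and ITPR1 were named after their values were seen; they had 1 and 4 counts over the macroH2A1.2 libraries against 271 and 269 in vector. CALB1, the calcium buffer calbindin, fell from 203 ± 71.5 to 0.0586 ± 0.0305 CPM (log2 fold change -11.67 ± 0.43, SE, adjusted p = 1.43e-05), and SPP1, the secreted protein osteopontin and among the 6 lowest adjusted p, from 176 ± 32.9 to 4.03 ± 0.952 CPM (log2 fold change -5.45 ± 0.23, SE, adjusted p = 1.43e-05). RPE65, the retinoid isomerase, was at least 268-fold lower. At the globin locus on chromosome 11, HBE1 was 1570-fold lower (95% counting interval 434 to 13000) and OR51B4 at least 204-fold lower; their annotated spans overlap, so their counts may share reads and are uncertain. The trefoil genes TFF1 and TFF2, which encode mucosal peptides, fell by 6.65 and 7.37 on the log2 scale. The cancer-testis gene MAGEC1, the imprinted gene PEG10, MMP28, AGMAT and FCER1G completed the 12, with log2 fold changes from -9.30 to -6.27. Among the 12 falls, CALB1 (-0.16), RPE65 (-0.35), HBE1 and OR51B4 (both -0.21) lay in windows shifted downward, and MAGEC1 (0.35) and AGMAT (0.19) in windows shifted upward, by their medians.

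**Figure D1:**
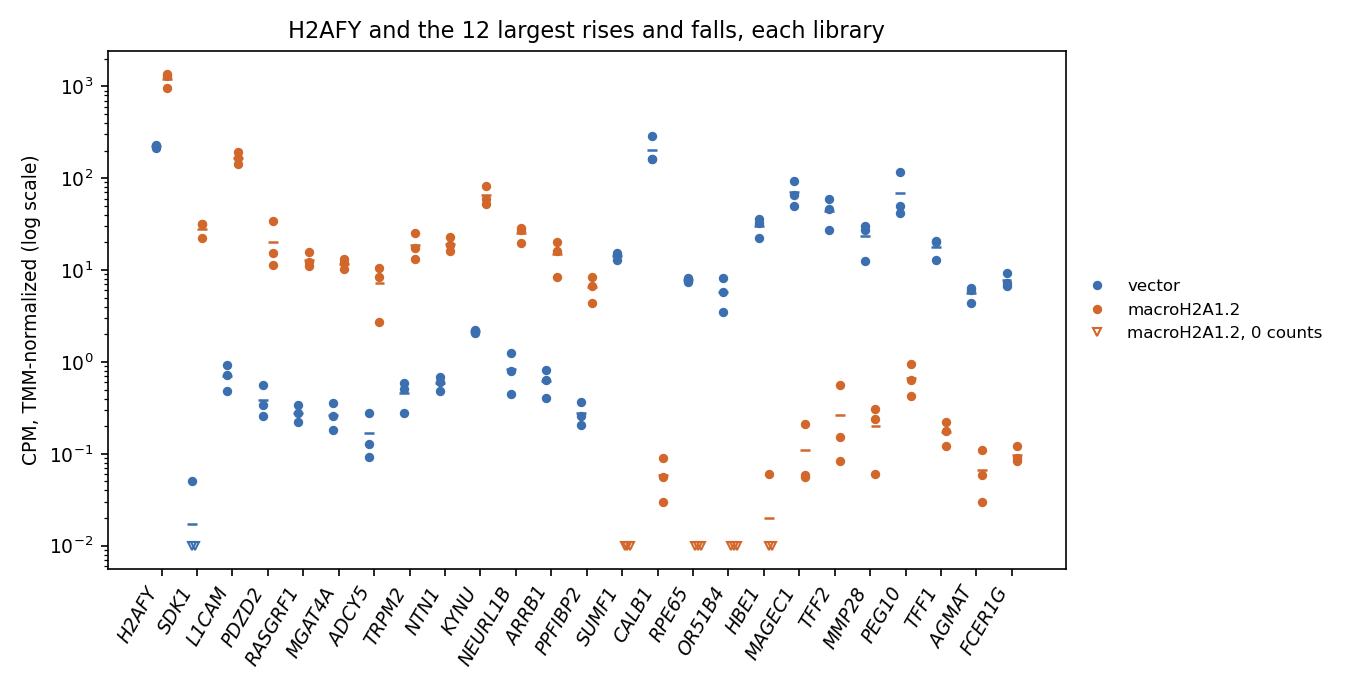
Points are the TMM-normalized CPM of each library on a log scale for H2AFY and the 12 largest rises and falls, with vector in blue and macroH2A1.2 in orange; horizontal ticks are group means of 3 libraries, and open triangles near the bottom mark libraries with 0 counts. In each gene shown, all libraries of one group lie above all of the other, and SUMF1, RPE65 and OR51B4 are at 0 in each macroH2A1.2 library.

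Neighbouring genes shifted together along the genome. Of 299 windows of about 50 tested genes, 95 had a median log2 fold change past the permutation test, 34 higher and 61 lower, with medians from -0.60 to 0.61. These windows held 31.7% of tested genes and 50.2% of called genes, and 33.5% of their genes were called against 15.4% elsewhere; windows picked for shifted log2 fold changes hold more called genes by construction. The stretches with the most windows (hg19) were 7989372 to 57724724 on chromosome 19, with a median of -0.30 over 900 genes, and 64043 to 55540603 on chromosome 16, with a median of -0.42 over 450 genes. Chromosome 6 had a median of 0.40 from 10723148 to 74127292 and of -0.42 from 90539613 to 171046865. Chromosome 7 had a median of 0.50 from 70972 to 56067874, a stretch that holds EGFR, and of -0.44 from 116451124 to 148923339. Outside the 95 windows, 1618 genes were called, 910 higher and 708 lower, and 744 of them changed at least 2-fold.

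**Figure D2:**
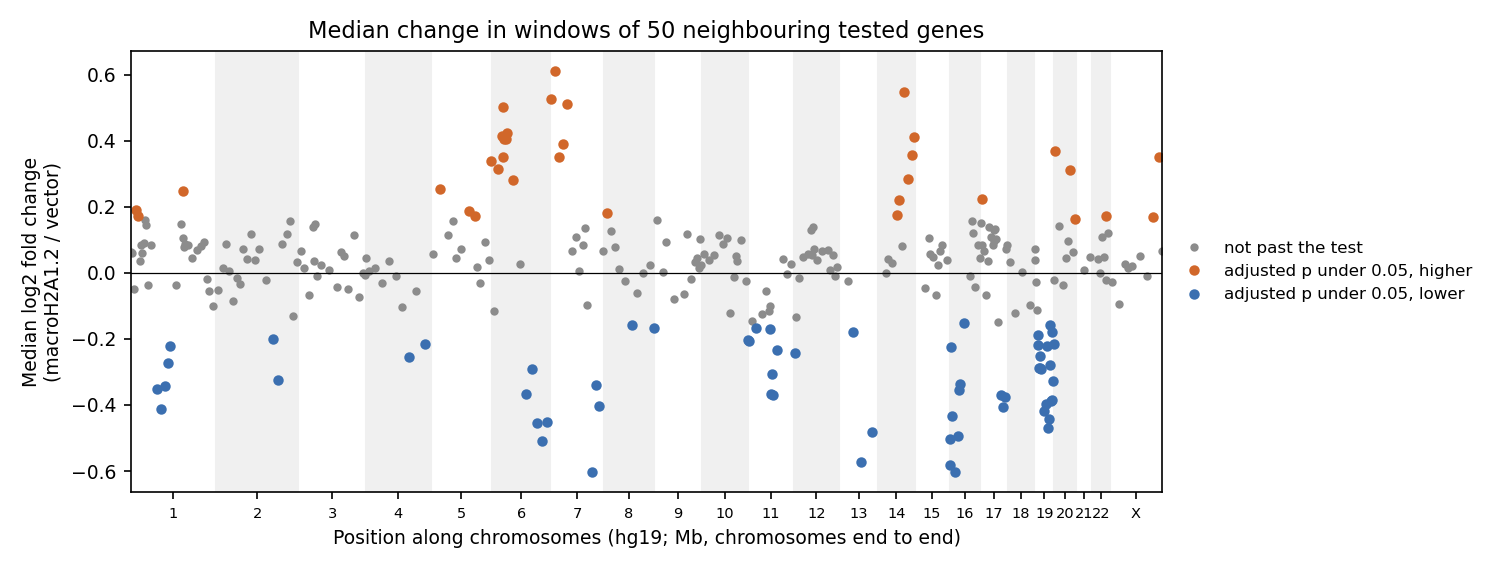
Each point is the median log2 fold change (macroH2A1.2 over vector) of a window of about 50 neighbouring tested genes, placed along the chromosomes laid end to end (hg19, Mb). Orange and blue points passed the permutation test as higher and lower, 34 and 61 of 299 windows, and gray points did not.

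Genes of the NRF2 and xenobiotic response, which encode antioxidant and detoxifying proteins, were lower: 16 of 34 tested members fell, 3 rose and 15 did not pass (21 lower and 3 higher adjusted over the list alone; 25 and 3 with the block). The list passed camera at the preset correlation (adjusted p = 1.95e-05). It did not pass with the estimated correlation, 0.332 (adjusted p = 0.796), or by fry (adjusted p = 0.068). GCLM, a subunit of the enzyme that limits glutathione synthesis, fell from 1136 ± 56.1 to 455 ± 59.3 CPM (log2 fold change -1.32 ± 0.12, SE, adjusted p = 0.000456). ALDH3A1, an aldehyde dehydrogenase, fell from 417 ± 104 to 35.6 ± 25.9 CPM, and the efflux pump ABCC1 and the aryl hydrocarbon receptor repressor AHRR fell by 1.26 and 1.02 on the log2 scale. The 3 that rose, named after their values were seen, were ABCC2 (0.99), GCLC (0.64) and TXNRD1 (0.44, log2). No list passed camera with an estimated correlation. Of the 19 called members, 7 lay in shifted windows, among them GCLM (-0.34), ABCC1 (-0.60) and GCLC (0.28).

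Nuclear genes of oxidative phosphorylation were also lower, by smaller amounts: 12 of 40 fell, 0 rose and 28 did not pass (14 lower adjusted over the list alone; 16 lower and 1 higher with the block). Camera gave an adjusted p of 0.000132 at the preset correlation of 0.01. With the estimated correlation, 0.00905, camera gave an adjusted p of 0.323, and fry gave one of 0.00395. The estimated correlation is no higher than the preset one, so a higher correlation between these genes does not account for that change. Its cause was not tested. UQCRC2, a subunit of complex III, fell from 200.2 ± 10.3 to 119 ± 0.975 CPM (log2 fold change -0.75 ± 0.084, SE, adjusted p = 0.000928), and NDUFA5, UQCRFS1 and NDUFS8 fell by 0.73, 0.68 and 0.65 on the log2 scale. Of the 12 called members, 9 lay in shifted windows, these 4 among them, with window medians of -0.49, -0.60, -0.42 and -0.31. Of the 13 mitochondrially encoded genes, 0 were called (camera adjusted p = 0.951). In the hypoxia and glycolysis list, 6 of 39 fell and 1 rose (camera adjusted p = 0.785; the same counts adjusted over the list alone; 9 lower and 7 higher with the block). The 6 included the glycolytic enzymes GPI (-0.96), GAPDH (-0.64) and TPI1 (-0.65, log2), and the hypoxia-induced carbonic anhydrase CA9 rose by 2.37; GPI and GAPDH lay in windows with medians of -0.40 and -0.24. The medians of the mitochondrially encoded (-0.024) and hypoxia (0.0086) lists had the opposite sign to their tests.

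TGF-beta targets were higher: 10 of 30 rose, 1 fell and 19 did not pass (10 and 2 adjusted over the list alone; 13 and 4 with the block). Camera gave an adjusted p of 0.0339 at the preset correlation and 0.778 with the estimated correlation, 0.0566. Fry gave an adjusted p of 0.0247. The camera adjusted p was 0.0667 without vector library 1, 0.0507 without macroH2A1.2 library 2 and 0.0575 without macroH2A1.2 library 3. LTBP2, a matrix protein related to TGF-beta binding proteins, rose from 135 ± 14 to 418 ± 10.7 CPM (log2 fold change 1.63 ± 0.10, SE, adjusted p = 8.44e-05). The BMP antagonist NOG rose by 2.79, the TGF-beta feedback gene PMEPA1 by 1.08 and the activin subunit INHBA by 1.79 on the log2 scale. ID1, named after its values were seen, was the member that fell (-1.06, log2). LTBP2 and INHBA lay in windows with medians of 0.55 and 0.39, and INHBA had an adjusted p of 0.0616 without the low-count filter.

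Matrix and mesenchymal genes moved in both directions. In the extracellular matrix and basement membrane list, 7 of 32 rose and 2 fell (9 and 5 adjusted over the list alone; 11 and 5 with the block; camera adjusted p = 0.0872, fry 0.00395). Besides TNC, the collagen gene COL12A1 rose from 9.7 ± 0.927 to 54.6 ± 16.3 CPM and THBS2, which encodes thrombospondin-2, rose by 5.42 on the log2 scale from 6 counts over the vector libraries, in a window with a median of -0.45. COL17A1, a hemidesmosomal collagen, fell by 1.82. Of the mesenchymal and EMT markers, 7 of 30 rose and 4 fell (9 and 4 adjusted over the list alone; camera adjusted p = 0.46), and the collagen genes COL5A1, COL6A2 and COL6A1 fell by 2.23, 1.12 and 0.91 on the log2 scale. VIM, the mesenchymal filament vimentin, was at 3.1 ± 2.08 and 7.84 ± 2.25 CPM (log2 fold change 1.32 ± 0.43, SE, adjusted p = 0.0655). Its adjusted p was 0.00227 with the block, 0.00612 with DESeq2 and 0.0383 with voom. Without vector library 1 its log2 fold change was 2.04 (adjusted p = 0.00484). The adjusted p was 0.239 without the low-count filter and 0.0885 to 0.184 without any other single library. CDH1, the epithelial adhesion gene E-cadherin, was at 316 ± 52.9 and 310.1 ± 43.8 CPM (adjusted p = 0.929), and its small difference turned sign with library size as the scaling. Of 35 epithelial markers 2 rose and 2 fell (the same adjusted over the list alone; 6 and 3 with the block; camera adjusted p = 0.667), with MUC1 at 2.46 and SPINT2, in a window with a median of -0.22, at -0.62 (log2).

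Among squamous and keratinocyte genes, 11 of 22 fell and 2 rose, the same adjusted over the list alone (camera adjusted p = 0.0617, fry 0.059, and 0.0361 by fry with the block). The keratins KRT17 and KRT13 fell from 109.7 ± 11.2 to 36.5 ± 2.51 CPM and from 79.8 ± 35 to 2.85 ± 2.14 CPM, and the integrin ITGB4, in a window with a median of -0.38, fell by 0.76 on the log2 scale; keratin genes have close relatives and their counts may share reads. TP63, a transcription factor of squamous epithelium, rose from 1.58 ± 0.642 to 12.6 ± 1.1 CPM, and S100A9, named after its values were seen, was the other that rose (1.99, log2, window median 0.25). Of 10 tested lung lineage and surfactant genes, 3 fell and 1 rose (the same adjusted over the list alone; 7 and 1 with the block; camera adjusted p = 0.204, fry 0.059, and 0.0193 by fry with the block). CEACAM6 fell from 1454 ± 431 to 443 ± 172 CPM (adjusted p = 0.0991 without the low-count filter) and the lineage factor GATA6 by 0.75 (log2), while AGER rose by 0.81; the windows of CEACAM6 and AGER had medians of -0.44 and 0.50. Of 11 neuroendocrine and neuronal genes 3 fell, SCG5, NRCAM and CHGA, and 0 rose (the same adjusted over the list alone; 3 lower and 1 higher with the block; camera adjusted p = 0.178, fry 0.0145); CHGA had an adjusted p of 0.054 without macroH2A1.2 library 1 and lay in a window with a median of 0.28. Of 14 stem cell associated genes 2 rose and 3 fell (the same adjusted over the list alone; camera adjusted p = 0.765), including SALL4 (-2.68) and SOX9 (1.16, log2, window median -0.41); the list's median was 0.050, its mean -0.34 and its test lower.

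EGFR, the mutated receptor of this line, rose from 804 ± 191 to 1359 ± 200.5 CPM (log2 fold change 0.76 ± 0.19, SE, adjusted p = 0.0226). Its window had a median of 0.51, and the adjusted p was 0.0946 without vector library 2, 0.0707 without macroH2A1.2 library 1 and 0.0572 without macroH2A1.2 library 3. In the list of ERBB receptors, ligands and MAPK feedback genes, 7 of 39 rose and 4 fell (the same adjusted over the list alone; camera adjusted p = 0.371). The immediate-early gene EGR3 rose by 3.90, and the ligand NRG1 and the ERK phosphatase DUSP5 fell by 1.23 and 0.91 on the log2 scale. Notch and Wnt pathway genes rose in 5 and fell in 3 of 25 (7 and 3 adjusted over the list alone; 9 and 6 with the block; camera adjusted p = 0.371): the Notch modifier LFNG rose by 2.36 and the target HEY1 by 2.04, while the ligand JAG2 fell by 2.27 and the target HES1 by 1.04. The windows of LFNG, HEY1 and JAG2 had medians of 0.53, -0.16 and 0.41. YAP/TAZ targets rose in 6 and fell in 4 of 23 (8 and 4 adjusted over the list alone; camera adjusted p = 0.425), with CRIM1 at 0.65 and F3, in a window with a median of -0.34, at -1.13 (log2).

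Interferon response genes rose in 7 and fell in 2 of 31, the same adjusted over the list alone (camera adjusted p = 0.0617). USP18, which restrains interferon signalling, fell by 1.75, and GBP2 and IRF1, in windows with medians of -0.41 and 0.17, rose by 1.64 and 0.95 on the log2 scale. Antigen presentation genes rose in 4 and fell in 1 of 18 (5 and 1 adjusted over the list alone; 6 and 3 with the block; camera adjusted p = 0.0872): the peptidase ERAP2 rose by 0.82 and the class I transactivator NLRC5 fell by 1.01 (log2; adjusted p = 0.0516 and 0.0636 without macroH2A1.2 libraries 1 and 2). NF-kB targets and secretory inflammatory genes rose in 3 and fell in 7 of 32 (4 and 8 adjusted over the list alone; 5 and 6 with the block; camera adjusted p = 0.622), and the chemokine CXCL1 fell from 1.56 ± 0.814 to 0.0578 ± 0.0269 CPM.

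Proliferation genes passed in few cases. Of 45 genes of G1/S and DNA replication, CCNE1 (-1.19) and RRM1 (-0.46, log2) fell and 0 rose (the same adjusted over the list alone; 2 lower and 1 higher with the block; camera adjusted p = 0.178). RRM1 had an adjusted p of 0.0732 and 0.0559 without macroH2A1.2 libraries 2 and 3, and the windows of CCNE1, RRM1 and CKAP2 had medians of -0.42, -0.21 and -0.57. Of 45 G2/M and mitosis genes, CKAP2 fell (-0.53, adjusted p = 0.023; 0.0617, 0.0544 and 0.0962 without vector library 1, macroH2A1.2 library 1 and macroH2A1.2 library 2), and 0 members passed adjusted over the list alone (8 lower and 2 higher with the block; camera adjusted p = 0.457). MKI67, the proliferation antigen, was at 195 ± 80.7 and 187 ± 45.5 CPM (SD, n = 3, adjusted p = 0.912). Of 30 p53 targets 3 rose and 5 fell (the same adjusted over the list alone; camera adjusted p = 0.677), with TP53I3 at -1.84 (log2). Of 37 homologous recombination and Fanconi genes 1 rose and 4 fell (1 and 3 adjusted over the list alone; 4 and 8 with the block; camera adjusted p = 0.257): RAD51C fell by 0.91 and XRCC3 rose by 0.42 on the log2 scale, in a window with a median of 0.41.

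Among 10 histone variant genes H2AFY rose, and H2AFZ, which encodes H2A.Z, and H3F3B, which encodes H3.3, fell by 0.88 and 0.78 on the log2 scale (1 and 2 also adjusted over the list alone; 2 and 2 with the block; camera adjusted p = 0.765). H3F3B, in a window with a median of -0.38, did not pass without vector library 1, vector library 2, macroH2A1.2 library 2 or macroH2A1.2 library 3 (adjusted p = 0.0974, 0.121, 0.12 and 0.108) or without the low-count filter (0.109), and both genes have processed copies that may share reads. Of 35 macroH2A chaperones, chromatin regulators and Polycomb genes 3 rose and 4 fell (the same adjusted over the list alone; 8 and 6 with the block; camera adjusted p = 0.738), including the Polycomb genes PHF1 (0.47) and RING1 (0.77, log2), both in windows with a median of 0.41. PARP1, whose product binds the macrodomain, was at 214 ± 12.2 and 187 ± 11.9 CPM (adjusted p = 0.18). Of 29 genes of the PARP family and NAD metabolism 5 rose and 6 fell (9 and 6 adjusted over the list alone; 9 and 7 with the block; camera adjusted p = 0.777). NAMPT, the salvage enzyme that limits NAD synthesis, fell from 819 ± 231 to 318 ± 28.5 CPM (log2 fold change -1.37 ± 0.21, SE, adjusted p = 0.00324).

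**Figure D3:**
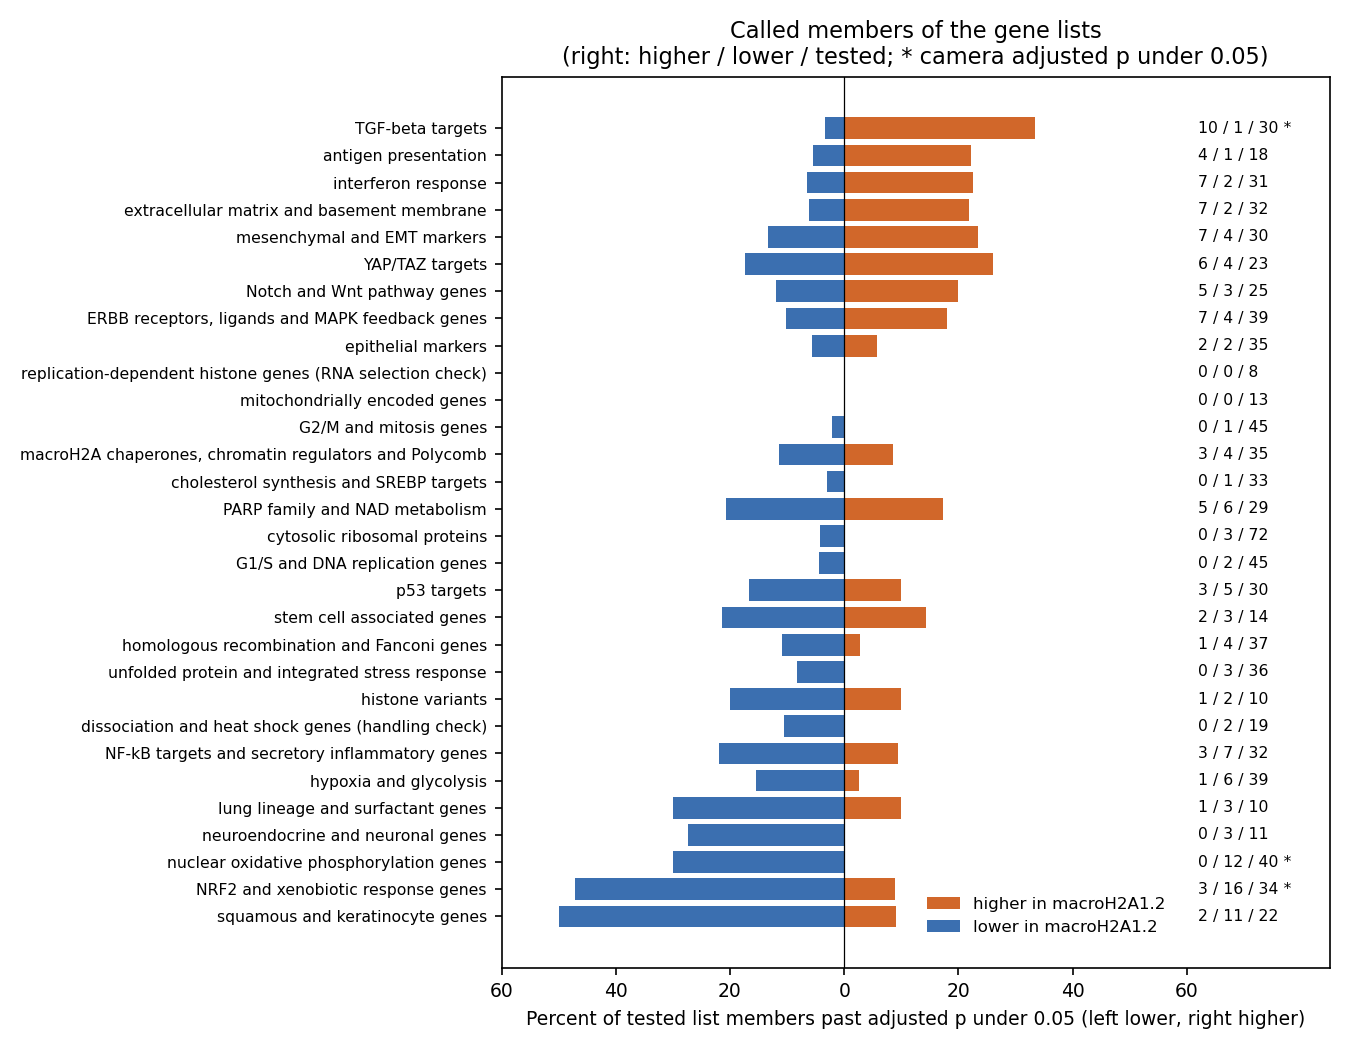
Bars give the percent of each list's tested genes that were called higher (orange, right) or lower (blue, left) in macroH2A1.2 cells, for the 30 lists with at least 5 tested genes; numbers at the right are genes higher, lower and tested. Asterisks mark the 3 lists past camera at the preset correlation, TGF-beta targets, nuclear oxidative phosphorylation genes and NRF2 and xenobiotic response genes; 0 lists passed with an estimated correlation.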

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

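Alternatives that used shifted windows, gene families, GC content or the block for windows were chosen after the data were seen. The H2AFY rise kept its direction and its call in each alternative run, with log2 fold changes from 2.345 to 2.577 when 1 library was left out. The count of called genes stayed within 1.5 times under other scalings, filters and tests: 3252 with RLE size factors, 3257 with the upper quartile, 3320 with library size alone, 3563 without a filter, 3803 with DESeq2 and 3257 with voom. Library size alone gave 1861 higher and 1459 lower, where TMM gave 1535 and 1713, and scaling moved the median of all genes by at most 0.0561 (log2). The replicate block raised the count to 5260 (2596 higher and 2664 lower). It changed the call of VIM and of no other named gene. It changed no list call by camera, and by fry those of the squamous and lung lists. Its counts of called members stand beside their lists or here where they changed. Higher and lower with the block, they were 10 and 6 for mesenchymal and EMT markers, 10 and 4 for the ERBB list and 9 and 2 for interferon response genes. They were 9 and 4 for YAP/TAZ targets, 4 and 6 for p53 targets, 3 and 4 for stem cell associated genes and 3 and 12 for squamous and keratinocyte genes. Leaving out 1 library gave 1837 to 3515 genes (838 to 1661 higher, 999 to 1854 lower), the lowest without macroH2A1.2 library 2 and then 1976 without vector library 2, and 943 to 1279 at least 2-fold (475 to 688 higher, 468 to 591 lower); the cause was not tested. Outside shifted windows 10512 genes were tested and 1618 called (910 higher and 708 lower), 744 of them at least 2-fold (385 and 359); the windows left out held 50.18% of the calls in 31.65% of the genes, as windows picked for their shift would. Lists past camera numbered 0 with an estimated correlation, 4 with fry, 6 without a filter, 5 after window shifts were removed and 2 to 8 without 1 library; the cause was not tested. Windows past the test numbered 60 with 100 genes each, of 145 windows, 140 with 25 genes each, of 606, and 90 to 97 without 1 library. The odds ratio of protein-coding genes went from 1.96 among called genes to 0.881 among those changed at least 2-fold; the cause was not tested. CDH1, not called in any setting, turned to 0.0325 (log2) with library size alone and ran from -0.1441 to 0.09538 without 1 library, above 0 without macroH2A1.2 library 1 (0.07009) or vector library 3. MKI67, also not called, ran from -0.2951 to 0.3122 without 1 library, above 0 without vector library 3, macroH2A1.2 library 1 (0.06312) or macroH2A1.2 library 2 (0.01241). Among named genes, calls were lost for 5 without a filter (H3F3B, INHBA, CEACAM6, CAV1 and MT1F), 1 with library size alone (RPS23) and 2 to 17 without 1 library, most without macroH2A1.2 library 2. In simulated counts for this comparison, with 15180 of 15380 genes unchanged, 32.89% of 1.5-fold changes were called. In the data 3248 genes were called, which makes the Benjamini-Hochberg cutoff less strict, so this share does not carry over directly.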

Other observations

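The tests of the block and of regional shifts for the oxidative phosphorylation and TGF-beta lists, the other transcripts of the SUMF1 segment and the runs of adjacent genes were chosen after the results they measure were seen. Of the lists not yet described, stress and metabolic genes passed in few cases. Of 36 genes of the unfolded protein and integrated stress response 3 fell and 0 rose (the same adjusted over the list alone; 4 and 2 with the block; camera adjusted p = 0.568): CBS, a transsulfuration enzyme, fell from 60.2 ± 30.1 to 4.77 ± 1.65 CPM (SD, n = 3), and DNAJC3 and SLC7A11 by 0.54 and 0.61 on the log2 scale. DNAJC3 lay in a window with a median of -0.48, and SLC7A11 had an adjusted p of 0.0604, 0.0509 and 0.0694 without vector library 2, macroH2A1.2 library 1 and macroH2A1.2 library 2. Of 33 cholesterol synthesis and SREBP targets FADS2 fell by 0.92 (1 also adjusted over the list alone; 2 lower and 5 higher with the block; camera adjusted p = 0.799), and the list's median was -0.033 though its test was higher. Of 3 tested metallothioneins MT1F fell by 2.28 (2 lower adjusted over the list alone and 2 with the block); this family shares much sequence, so its counts are uncertain. MT1F had an adjusted p of 0.0513, 0.0521 and 0.0507 without vector library 2, macroH2A1.2 library 2 and macroH2A1.2 library 3, and of 0.0668 without the low-count filter. KEAP1, the inhibitor of NRF2, named after its values were seen, was lower in macroH2A1.2 cells (log2 fold change -0.81 ± 0.11, SE, adjusted p = 0.00214, window median -0.19), and NFE2L2, which encodes NRF2, had a log2 fold change of -0.40 ± 0.15 (SE, adjusted p = 0.109, window median -0.32).

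Of 72 cytosolic ribosomal protein genes 3 fell and 0 rose (1 lower adjusted over the list alone; 16 lower and 7 higher with the block; camera adjusted p = 0.741); RPS2 fell by 0.70 on the log2 scale, in a window with a median of -0.50. Of 8 replication-dependent histone genes, a check on RNA selection, 0 were called (1 higher with the block; camera adjusted p = 0.46). Of 19 dissociation and heat shock genes 2 fell, HSPA4L (-2.94) and FOSB (-0.91, log2), and 0 rose (1 lower adjusted over the list alone; 3 lower and 1 higher with the block; camera adjusted p = 0.777); FOSB did not pass without vector library 1, vector library 2, macroH2A1.2 library 2 or macroH2A1.2 library 3 (adjusted p = 0.111, 0.0951, 0.0992 and 0.0854). HSPA4L and FOSB lay in windows with medians of -0.26 and -0.28. That list's median was 0.061, its mean -0.096 and its test lower. Markers of other cell types were mostly too low to test, with 4 of 12 fibroblast, 3 of 16 leukocyte and 4 of 10 endothelial genes tested, and they moved apart. Among leukocyte markers FCER1G fell and CSF1R rose (2.70, log2). Among endothelial markers CDH5 rose from 2.56 ± 0.128 to 29 ± 13.3 CPM and ROBO4 by 3.05, while ESAM fell. Of the fibroblast markers 0 were called (1 lower with the block).

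The most widespread pattern was that of 95 windows of neighbouring genes whose log2 fold changes shifted together. The tables argue against GC content bias: 89.47% of these windows stayed past the test after the trend on transcript GC was removed. A difference in gene copy number between the selected lines is a candidate explanation: in 97.89% of the windows both the more and the less expressed genes had the window's sign, and in 100% of 63 adjacent pairs of shifted windows the sign was shared, against a mean of 53.7% over permuted signs (p = 1e-04, the smallest the permutations can give). Windows picked for their shift favour the first of these values, and any broad regional cause would give both, so neither parts copy number from a change of chromatin. Joined stretches of at least 3 windows had median linear ratios from 0.722 to 0.82 or from 1.32 to 1.42. Without DNA data these do not part copy number from chromatin either. Broad lowering by macroH2A1.2 itself stays open for the 61 lower windows, 64.21% of those shifted. The 34 higher windows, with medians up to 0.61, argue against it as the whole cause, provided that TMM scaling set unchanged genes at 0. Log2 fold changes are relative to that scaling, and these counts alone cannot show whether it did. Each group is taken as 1 line, whether clone or pool, without DNA data here.

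Of the lists past camera, the lower NRF2 list came first. Without the AKR1C, AKR1B and UGT1A families, whose members may share reads, it kept a camera adjusted p of 0.000243 at the preset correlation (range over this list's alternatives 3.13e-09 to 0.796). Camera at that setting passed more lists in every other split of the libraries, so this does not exclude read sharing as a cause of the list result. The called members GCLM, ABCC1, AHRR and ALDH3A1 lie outside these families, so read sharing within them does not account for those falls. For this list the block gave a camera adjusted p of 2.59e-07, and of 0.743 with an estimated correlation. Each number occurs once in each group, so the block cannot test differences between same-numbered libraries. Subtracting each gene's window median left 92.7% of the NRF2 list's median (-0.555, 95% bootstrap interval -0.678 to -0.416). For the oxidative phosphorylation list it left 121% (-0.22, interval -0.266 to -0.149). The bootstrap treats genes as independent. These values argue against regional shifts as the whole cause of the list medians. Of the members, 10 of 34 and 12 of 40 lay in shifted windows, so the medians rest mostly on other genes. They do not speak to the called members, of which 7 of 19 and 9 of 12 lay there. The subtraction left 76.4% of the TGF-beta list's median (0.19, interval 0.0162 to 0.528) and a camera adjusted p of 0.0213. Without vector library 1 the median left was 0.106 (camera adjusted p = 0.0873). Without macroH2A1.2 library 2 it was 0.115 (camera adjusted p = 0.0525), so regional shifts stay open for that list. These list calls were made by camera at a preset correlation and were lost with an estimated one. Other splits of the libraries, given below, passed more lists.

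A further pattern was 5 protein-coding genes at 5 CPM or more in one line with at most 3 counts over the libraries of the other: HBE1, SUMF1, RPE65 and OR51B4 in macroH2A1.2 and SDK1 in vector cells. Depth is excluded by the library sizes: each library held at least 32356038 counts, so the limit of 5 CPM itself keeps the expected counts high. The lowest count expected at the other group's level was 598.3. Loss of the surrounding region stays open: the flanking genes' median log2 fold change toward the line at 0 was 0.556 (quartiles -0.0045 to 1.16). This median pools unlike loci. HBB (-1.3) and TRIM6 (0.634) were flanks of both HBE1 and OR51B4, and ITPR1, itself near 0 counts, was a flank of SUMF1. The flanks of RPE65 were at -0.722 and -0.688 and those of SDK1 at 0.165 and 0.424 (log2, macroH2A1.2 over vector). Around SUMF1 a segment of chromosome 3 (hg19 3742498 to 4889524) held 1997 counts of SUMF1, SETMAR and ITPR1 in vector and 5 in macroH2A1.2 libraries, while the flanking genes CRBN (0.061) and BHLHE40 (0.089, log2) did not pass the test. A deletion of this segment in the macroH2A1.2 line is a hypothesis that these counts cannot part from joint silencing: the segment's other annotated genes had 7 counts in vector and 1 in macroH2A1.2 libraries, too few to decide.

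Runs of at least 3 adjacent tested genes, all changed at least 8-fold one way, numbered 3 against a mean of 0.015 over 1000 permuted gene orders (permutation p = 0.001, the smallest these can give), with both limits set after the SUMF1 segment was seen. They were that segment, the overlapping genes around HBE1 and the protease inhibitor genes SERPINA1, SERPINA5 and SERPINA3 on chromosome 14, which were higher in macroH2A1.2 cells, SERPINA1 with an adjusted p of 0.0575. Because the segment prompted the test and the genes around HBE1 may share reads, the permutation p largely restates the observation.

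The 6 libraries make 10 splits into 3 and 3, too few for a share under 0.05. Every other split puts libraries of both lines in each group, so the difference between the lines enters its error. Few genes could then be called whatever the cause, with or without the block, so the gene counts below do not test chance. In 1 of the 10, the real one, as many genes were called: 3248, with 2 as the highest of the others. For genes changed at least 2-fold the count was again 1 of 10, with 1195 in the real split and 2 as the highest other. For lists past camera it was 10 of 10: the real split passed 3 lists and the highest other 17. Every other split thus passed more lists than the real one, from 5 upward, which points to a structure of the libraries whose cause was not tested. Of the other splits, 3 part all pairs of same-numbered libraries as the real one does; with the block they called 0 genes and passed 17, 7 and 9 lists, against 5260 genes and 3 lists for the real split. The remaining 6 part 1 pair and called at most 2 genes.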
